A study of Homo sapiens with 16 samples.

How the data were processed

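Total RNA from RPE cells was sequenced after sorting. The cells were a control line and a line with stable KDM4A overexpression, in 2 cultures each, per the labels. Cells were stained with a Hoechst dye and sorted by DNA content into G1, early and late S and G2/M, and stranded libraries were made after depletion of ribosomal RNA, per the labels' protocols. This gives 16 libraries in 8 groups of 2. Within a genotype, the replicate number names the culture that was sorted into all 4 phases, per the labels' source names.

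The deposited files hold raw counts, 1 file per library, for 57773 Ensembl gene IDs, followed by 5 totals of reads that were not assigned to a gene. The authors aligned reads to hg19 with STAR and counted them with HTSeq, per the submitters' processing notes. The versions of STAR and HTSeq, the strand setting and the annotation release are not given in the sources used here. The totals of unassigned reads were kept out of library sizes and tests. Of the gene IDs, 52338 were named through GENCODE release 29 and 5435 were left without a name; no coordinates are given, because that release uses another genome build. The counts in genes ranged from 7197126 to 18517294 per library. Reads in no gene took 22.9% to 52.3% of each file, reads with more than 1 alignment 15.1% to 19.6%, and ambiguous reads 1.92% to 4.91%. The 10 most counted genes took 15.5% to 33.6% of the gene counts, protein-coding genes 64.7% to 84.2%, and the mitochondrially encoded genes were listed at 0 in every library. Intervals and floors cover counting error only.

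Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and 14211 genes were tested with the quasi-likelihood F test in 1 model of all 16 libraries and 8 groups, with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.209, and 0.109 with cultures as a block. The comparisons were KDM4A against control within each phase, each later phase against G1 within each genotype, and the difference of these changes between genotypes, singly and with 3 together. Since the culture carries the genotype, the counts of the 4 phases were also added per culture and 2 profiles were compared with 2, over 16900 genes. All tests are two-sided. Values are given as log2 fold changes with their standard errors, or as TMM CPM with the standard deviation. A gene is said to rise or fall where its adjusted p was under 0.05.

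Gene lists were fixed before the files were examined and tested where at least 5 members were tested, which gave 30 lists in a comparison, or 31 with the phases summed, and 421 list tests over 14 comparisons. The test was camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Printed here are the canonical histones and their subsets, the S phase and G2/M genes, origin licensing and firing, homologous recombination and fork protection, p53 targets, cyclins, CDK inhibitors and E2F factors, ribosomal proteins, cholesterol synthesis and extracellular matrix. The lists overlap: the p53 targets and the cyclins list both hold CDKN1A, for example. Genes were named by a rule on adjusted p, mean log2 CPM of at least 2 and separation of the libraries, or because a comparison had few calls, the latter decided after the values were seen. A gene with 0 counts in both libraries of a group was compared with a floor of 3 counts over the group.

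Within a genotype, deviations from the group mean correlated between phases of the same culture (r from 0.443 to 0.798 over 6 pairs of phases in control cells, and from 0.351 to 0.664 in KDM4A cells), so phase comparisons are also given with a culture replicate block. Across genotypes the same number did not go together (r from -0.316 to 0.019 in 4 pairs), so the numbers were not taken to pair control with KDM4A cultures. The alternatives were DESeq2 1.42.0, its size factors in edgeR, library size without further scaling, no filter on low counts, protein-coding genes alone, the libraries of 1 phase alone, a replicate block, leaving out each library, and leaving out control culture 1. For the summed phases the average of the 4 within-phase contrasts was also taken. A fit that leaves 1 library in a group takes its spread from the other groups, so its calls assume an equal spread. The fits that leave out a library had no culture block. A change from G1 in them therefore also carries differences between cultures. Protein-coding genes alone, leaving out control culture 1 and a block with crossed replicate numbers in early S were added after the values were seen.

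The tests were tried on simulated data drawn from the real means and library sizes, with no culture effect, so the false calls below leave out the correlation of phases within a culture. For KDM4A against control in late S, with 14024 genes, 34 of 100 genes changed 2-fold and 79 of 100 changed 4-fold were found, with 7 false among 120 calls. For the difference between genotypes, 14 and 65 were found, with 4 false among 83. For G2/M against G1 in control cells, with 13946 genes, 34 and 81 were found, with 1 false among 116. For the summed phases, with 14209 genes, 80 and 100 were found, with 9 false among 189. A shift of 0.5 put on 23 genes gave a median of 0.43. The camera adjusted p was 7.9e-07 with the preset correlation and 0.0078 with an estimated one. With the preset correlation, 1 of 24 other lists was also found. Genes were drawn independently of each other, so this does not show how the estimated correlation fares on correlated genes. Explanations for the late S peak of control culture 2 were drafted but not tested.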

Results

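RNA was sequenced from RPE cells, a retinal pigment epithelial cell line, that either overexpressed the lysine demethylase KDM4A in stable form or served as controls, per the labels. There were 4 cultures, 2 per genotype, and each was sorted by DNA content into G1, early and late S and G2/M cells. The 16 libraries therefore form 8 groups of 2, and all values below rest on n = 2 libraries per group unless another number is given. The counts assigned to genes ranged from 7197126 to 18517294 per library, with a median of 11621586. Of the reads in each file, 47.4% to 72.3% were not assigned to a gene. From G1 to G2/M, reads in no gene rose from 22.9% to 37.8% and from 39.7% to 51.0% in control cultures 1 and 2. They rose from 36.6% to 41.8% and from 37.7% to 41.2% in KDM4A cultures 1 and 2. The first principal component of the 2000 most variable genes held 37.9% of their variance and separated control culture 1, in all 4 phases, from the other 3 cultures. The second held 18.9% and ordered the phases within every culture.

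**Figure D1:**
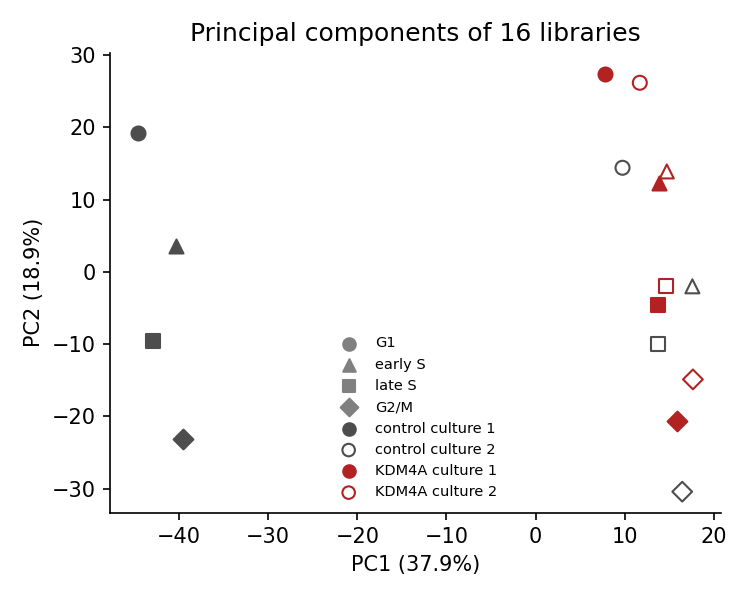
Principal components 1 and 2 of the 16 libraries, from the log2 CPM of the 2000 most variable genes, with the percent of variance on each axis. Each point is a library, coloured by genotype, shaped by phase and filled for culture 1; control culture 1 lies between -44.59 and -39.55 on component 1 and the other libraries between 7.76 and 17.65.

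The first question was whether the sorted KDM4A cultures carried more KDM4A transcript than the control cultures, which checks the labels. KDM4A (ENSG00000066135), a demethylase of histone lysines, was higher in all 8 KDM4A libraries than in any control library, at 311 to 919 against 28.2 to 55.8 CPM (counts scaled to a common library total with TMM factors). In G1 the mean was 588 ± 318 CPM (SD) in KDM4A cells and 35.7 ± 1.27 in control cells, a ratio of 16.5. The ratio was 12.9 in early S, 13.6 in late S and 13.7 in G2/M. The log2 fold change was 4.04 ± 0.47 (SE) in G1 with an adjusted p of 0.0048, and it lay between 3.69 and 3.78 in the other phases. KDM4A culture 2 held 1.72 to 2.24 times as much KDM4A transcript as KDM4A culture 1, depending on the phase. Of the relatives of KDM4A, none passed in any phase by edgeR. KDM4B and KDM4C stayed at 13.9 to 21.7 CPM as group means, KDM4D at 0.550 to 1.42, and KDM4E was listed at 0 in every library.

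**Figure D2:**
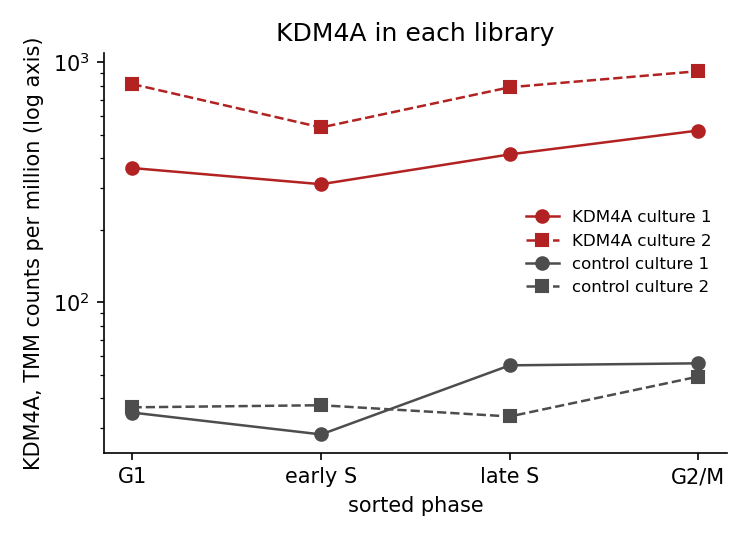
KDM4A in TMM CPM on a log axis against the sorted phase, 1 point per library and 1 line per culture. The KDM4A cultures lie between 311 and 919 and the control cultures between 28.2 and 55.8.

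The second question was which other genes differed between KDM4A and control cells within a phase. A small set rose with KDM4A, and the same names recurred across the phases. The phases are fractions of the same 4 cultures, so this recurrence is no independent support. The standard errors and adjusted p within a phase pool the spread of all 16 libraries, as if phases of a culture were independent. With the phases summed per culture, only CHFR passed, as given below. With the libraries of 1 phase alone, 5 genes passed in G1 and 0 in each other phase. PLTP (ENSG00000100979), which encodes a phospholipid transfer protein, and PLA2R1 (ENSG00000153246), a receptor for secreted phospholipase, rose in all 4 phases. CHFR (ENSG00000072609), a ubiquitin ligase of an early mitotic checkpoint, also rose in all 4. MSRB1 (ENSG00000198736), a methionine sulfoxide reductase, rose in G1, early S and late S, and TSPOAP1 (ENSG00000005379), a partner of a mitochondrial membrane protein, rose in G1 and late S. These genes are named because the lists were short enough to give whole, KDM4A, PLTP and PLA2R1 also because they met a rule on level.

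PLTP rose by 3.40 ± 0.36 on the log2 scale in G1 and 3.90 ± 0.41 in G2/M, with adjusted p of 0.0034 and 0.0037, and its fold changes in early S and late S were 3.48 and 3.36. PLTP stood at 0.653 to 1.38 CPM in the 8 control libraries and at 8.06 to 16.1 in the 8 KDM4A libraries. PLA2R1 rose by 3.03 ± 0.39 in G1 and by 3.08, 3.81 and 3.54 in early S, late S and G2/M, with adjusted p between 0.0046 and 0.0092. CHFR had 0 to 2 counts in each control library and 63 to 115 in each KDM4A library, with adjusted p between 0.0034 and 0.0054. In late S and G2/M, where both control libraries held 0 counts of CHFR, it was at least 34.6-fold and 37.6-fold higher in KDM4A cells, taking 3 counts over the group as the floor. MSRB1 had 0 to 4 counts in each control library and 23 to 50 in each KDM4A library. In late S, with 0 counts in both control libraries, MSRB1 was at least 12.8-fold higher against the same floor. The adjusted p of MSRB1 was 0.0112 in G1, 0.0157 in early S and 0.0237 in late S. TSPOAP1 rose by 3.39 ± 0.53 in G1 (adjusted p = 0.0419) and by 4.03 ± 0.57 in late S (adjusted p = 0.0231). The files give one further gene, ENSG00000198366, that the names used here do not cover. Of the 70 canonical histone genes listed, 35 could not be matched either, so the names used here cannot tell whether this gene is one of them. An annotation of hg19, the genome build of the counts, would be needed for that. It rose by 3.58 ± 0.43 in G1 (adjusted p = 0.0053) and by 3.91 ± 0.46 in early S (adjusted p = 0.0054).

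In numbers, edgeR found 7 genes higher in KDM4A cells in G1, 6 in early S, 6 in late S and 4 in G2/M, and 0 lower in any phase. At an unadjusted p under 0.05 there were 509, 360, 471 and 434 genes in either direction. DESeq2 gave 16 higher and 4 lower in G1, 12 and 2 in early S, 13 and 1 in late S, and 13 and 1 in G2/M. Leaving out a control library left few calls. The count was 1 without control G1 replicate 1 and 0 without replicate 2; 1 without control early S replicate 1 and 0 without replicate 2; 0 without either control late S library; and 0 without control G2/M replicate 1 and 2 without replicate 2. Without KDM4A replicate 2 it was 4 in G1, 3 in early S, 3 in late S and 2 in G2/M.

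Gene groups shifted between the genotypes by small amounts. The targets of p53, a stress response list that holds CDKN1A and MDM2, were lower in KDM4A cells in early S, with a median log2 fold change of -0.28 over 23 genes, 20 of them negative. This was the only list in the 4 within-phase comparisons to hold with a correlation estimated from the data (camera adjusted p = 3.3e-06, and 0.0397 with an estimated correlation), although fry gave 0.145 and 0 of the 23 genes passed alone by edgeR. With control early S replicate 2 left out the preset test gave 0.0191, and scaled by size alone the median was -0.164. In G1, the S phase genes (median -0.28, 36 of 42 negative) and the origin licensing and firing genes (median -0.31, 23 of 26 negative) were lower with the preset correlation, at adjusted p of 1.3e-04 for each and 0.631 for each with an estimated correlation. Cholesterol synthesis genes had medians of -0.33, -0.35, -0.30 and -0.30 in G1, early and late S and G2/M, with adjusted p from 7.6e-04 to 0.0199 and from 0.631 to 0.812 with an estimated correlation. Ribosomal protein genes had a median of -0.22 in late S, 73 of 77 negative (adjusted p = 4.1e-06, and 0.812 with an estimated correlation). Scaled by size alone that median was -0.003, as the median of all genes then moved by 0.212; without KDM4A late S replicate 1 it was -0.055 (adjusted p = 0.0927), and without KDM4A late S replicate 2 it was -0.356. Control late S replicate 2 had the lowest TMM factor, 0.841, and 33.6% of its counts in 10 genes. Extracellular matrix genes were higher in G1 by a median of 0.30 over 21 genes (adjusted p = 0.0107, and 0.631 with an estimated correlation). The G1 shifts and the cholesterol shifts rested on control culture 1. Without control G1 replicate 1 the G1 medians were 0.004 for the S phase genes, -0.033 for origin licensing and firing, 0.043 for cholesterol synthesis and 0.023 for extracellular matrix, with adjusted p from 0.509 to 0.823. Without control G1 replicate 2 they were -0.501, -0.523, -0.552 and 0.645. The cholesterol medians were -0.006, 0.022 and 0.005 without replicate 1 of control early S, late S and G2/M, and -0.534, -0.575 and -0.465 without replicate 2; in late S it was -0.102 when scaled by size alone. Without KDM4A replicate 1 of the phase the S phase genes in G1 (adjusted p = 0.101) and cholesterol synthesis in G1, early S and G2/M (0.0536 to 0.0986) no longer passed, and extracellular matrix did not without KDM4A G1 replicate 2 (0.209). The preset correlation gave 11, 6, 6 and 10 of 30 lists in G1, early and late S and G2/M, an estimated correlation 0, 1, 0 and 0, and fry 0 in each.

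When the 4 phases of each culture were added, giving 2 profiles against 2, CHFR alone rose (adjusted p = 0.0108). The control libraries held 5 counts of CHFR in all and the KDM4A libraries 676, too few in control cells for an exact fold. KDM4A itself reached a log2 fold change of 3.85 ± 0.36 and an adjusted p of 0.0611 there, shared by PLTP at 3.46 and PLA2R1 at 3.28. By edgeR 1 gene was higher and 0 lower of 16900 tested, with 512 at an unadjusted p under 0.05; DESeq2 gave 33 and 6. The edgeR count was 64 without control culture 1 and 1341 without control culture 2, 5 without KDM4A culture 1 and 3 without KDM4A culture 2; in these fits the genotype left with 1 profile is assumed to vary like the other. With a replicate number as a block the count was again 1 and 0. With protein-coding genes alone it was 0 and 0 of 12440 tested.

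The third question was which genes followed the sorted phase within a genotype. In early S, the mitotic kinase gene CDK1 and a few genes of DNA replication and repair rose from G1 in both genotypes, while the mitotic cyclin CCNB1 fell. CDK1 rose by 2.02 ± 0.31 in control cells (adjusted p = 0.0226) and 2.09 ± 0.32 in KDM4A cells (adjusted p = 0.0228). HELLS, a chromatin remodeller, rose by 1.40 and 1.46 in control and KDM4A cells, and BRCA1 by 0.98 and 1.15. TICRR, which acts in origin firing, rose by 1.17 and 1.30. BRCA2 and ESCO2 rose by 1.69 and 1.65 in control cells, and POLQ by 1.40 in KDM4A cells. CCNB1 fell by 1.15 and 1.11 in control and KDM4A cells, and CCNB2, CDCA3 and PRC1 fell in control cells by 0.95, 0.74 and 0.71. The S phase genes had a median rise of 0.29 in control and 0.52 in KDM4A cells over 42 genes, with adjusted p of 2.2e-05 and 1.3e-15, and 0.924 and 0.369 with an estimated correlation. The control median was 0.08 without control early S replicate 1, 0.02 without control G1 replicate 2, 0.617 without control G1 replicate 1 and 0.559 without control early S replicate 2. These fits had no culture block, so they also carry the difference between the control cultures. Within cultures 1 and 2 the medians were 0.281 and 0.279 in control cells, and 0.55 and 0.535 in KDM4A cells. Of the 42, 3 and 2 genes rose, or 14 and 17 adjusted over the list alone. The homologous recombination and fork protection genes had medians of 0.36 and 0.47 over 28 genes (adjusted p = 2.2e-05 and 1.4e-13, and 0.674 and 0.224 with an estimated correlation), and 0.189 in control cells without control early S replicate 1.

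In control cells 143 genes rose and 7 fell from G1 to early S, and in KDM4A cells 30 rose and 1 fell. Since each culture was sorted into all 4 phases, a fit with the culture replicate block compares phases within cultures. It gave 1355 and 545 in control cells and 557 and 146 in KDM4A cells, and it contained every gene of the fit without the block. Leaving out 1 library gave 0 to 392 genes in control cells, 0 of them without either control G1 library, 9 without control early S replicate 1 and 392 without control early S replicate 2. In KDM4A cells it gave 0 or 1.

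In late S, genes of mitotic entry had already risen in both genotypes. CDK1 rose by 2.50 ± 0.32 in control cells (adjusted p = 0.0017) and 3.15 ± 0.33 in KDM4A cells (adjusted p = 2.4e-04). TOP2A, the decatenating topoisomerase, rose by 2.33 and 2.56, and the ubiquitin-conjugating enzyme gene UBE2C by 2.13 and 2.32. The centromere chaperone gene HJURP rose by 2.13 and 2.45, and the spindle genes FAM83D and BORA by 2.45 and 2.21 in control and 2.50 and 2.56 in KDM4A cells. CCNA2 rose by 1.41 in both genotypes. The G2/M genes had a median rise of 1.09 in each genotype over 54 genes. Of these, 27 rose in control and 30 in KDM4A cells, and the list held with an estimated correlation (adjusted p = 0.0159 and 0.025). The p53 targets rose by medians of 0.41 and 0.33 (adjusted p = 0.038 and 0.025 with an estimated correlation), among them CDKN1A, by 1.12 and 1.50, and MDM2, by 1.05 and 1.07. The list of cyclins, CDK inhibitors and E2F factors held as well, with medians of 0.21 and 0.29 (adjusted p = 0.0381 and 0.025 with an estimated correlation), but with the preset correlation it did not pass in control cells without control late S replicate 1 (adjusted p = 0.13) or control G1 replicate 2 (0.158). Scaled by size alone, the control medians were 0.242 for the p53 targets and 0.081 for the cyclins list, and the latter was 0.048 with no filter on low counts. In control cells TEF, IL1B and E2F2 fell by 1.48, 1.43 and 1.38, and in KDM4A cells ZHX2 and ASB13 fell by 1.47 and 1.36. L3MBTL3 fell by 1.26 and 1.60. In all, 129 genes rose and 16 fell in control cells, and 253 rose and 24 fell in KDM4A cells; the culture replicate block gave 663 and 231, and 1044 and 533. The control count was 31 and 59 without control G1 replicates 1 and 2 and 61 without control late S replicate 2, and the KDM4A count was 84 to 124 without any 1 of its 4 libraries.

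In G2/M, mitotic genes stood above their G1 level and the cyclin E genes below it. In control cells FAM83D rose by 3.15 ± 0.25, TOP2A by 3.11 ± 0.24 and MKI67 by 2.83 ± 0.31, with adjusted p of 2.0e-05, 1.8e-05 and 1.9e-04. In KDM4A cells CDK1 rose by 3.39 ± 0.33 (adjusted p = 6.4e-05), FAM83D by 3.32, BORA by 3.29 and HJURP by 3.06. The helicase gene PIF1 rose by 2.82 in control and 3.18 in KDM4A cells. The centromeric histone gene CENPA rose by 2.22 and 2.15. The cyclin genes CCNE1 and CCNE2 fell by 2.33 and 2.33 in control cells, and by 2.92 and 1.79 in KDM4A cells. The uracil glycosylase gene UNG fell by 2.33 and 1.73, and the histone mRNA binding protein gene SLBP by 1.09 and 0.90. Of the 54 G2/M genes, 43 rose in each genotype, with medians of 1.50 and 1.60 (adjusted p = 0.0412 and 0.0224 with an estimated correlation). Ribosomal protein genes fell by medians of 0.67 and 0.65, 75 and 76 of 77 negative (adjusted p = 1.6e-12 and 6.5e-14, and 0.622 and 0.513 with an estimated correlation); the control fall was 0.44 without control G1 replicate 1 and 0.441 without control G2/M replicate 2. In all, 1187 genes rose and 670 fell in control cells, and 823 rose and 345 fell in KDM4A cells. The culture replicate block gave 2608 and 2546, and 2217 and 2152. Leaving out any 1 of the 4 libraries gave 347 (control G1 replicate 1) to 1055 in control cells and 228 (KDM4A G1 replicate 1) to 758 in KDM4A cells.

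**Figure D3:**
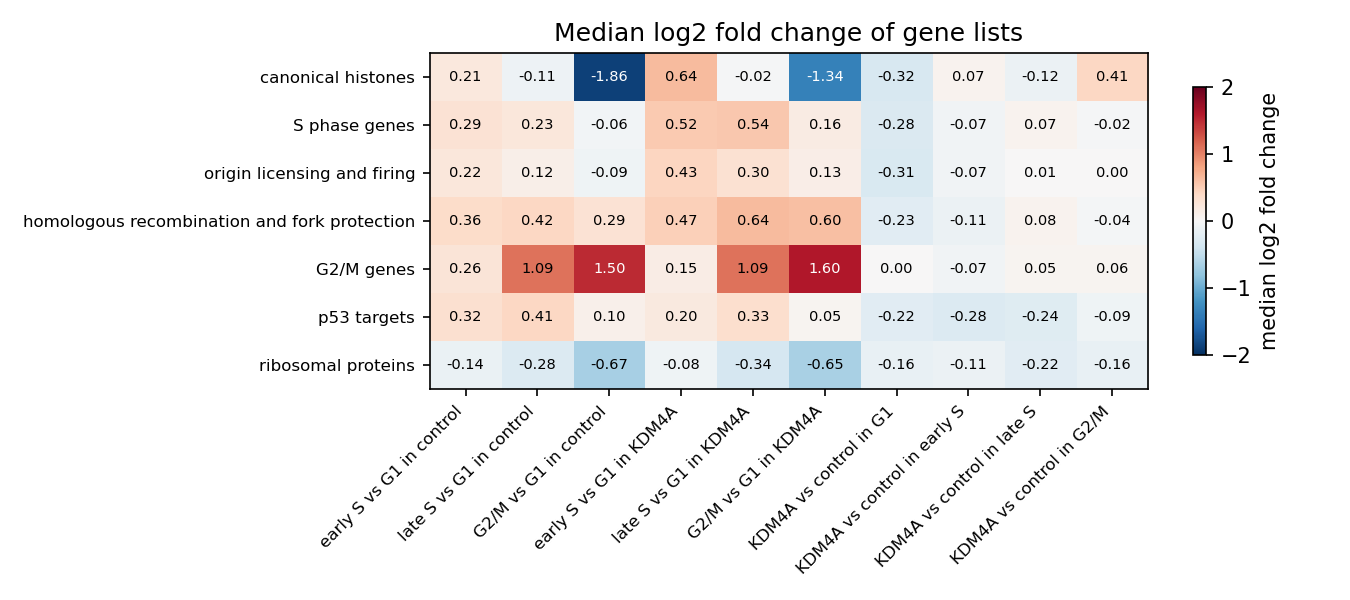
Median log2 fold change of 7 gene lists, in rows, over 6 comparisons of a phase with G1 and 4 comparisons of KDM4A with control cells, in columns. The canonical histones fell in G2/M by medians of 1.86 in control and 1.34 in KDM4A cells, and the G2/M genes rose by 1.50 and 1.60.

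The title of the series concerns the replicative canonical histone genes, the multi-copy genes that supply histones during DNA replication. Of 70 such genes listed, 35 could be matched by name. All 35 enter the sums below, and 25 held enough counts to be tested in the fit of 16 libraries. Tested were 5 of 6 listed H1, 6 of 17 H2A, 9 of 18 H2B, 1 of 14 H3 and 4 of 15 H4 genes. The medians of the list therefore rest mainly on H1, H2A and H2B genes. The 35 that could not be matched are not analysed here. Reads that fitted more than 1 place were left out of the deposited counts, so near-identical copies are counted in part. Summed over the list, canonical histones held 0.320% ± 0.061 (SD) of the counts in control G1, 0.397% ± 0.153 in early S, 0.298% ± 0.047 in late S and 0.115% ± 0.000495 in G2/M. In KDM4A cells the shares were 0.273% ± 0.062, 0.425% ± 0.027, 0.313% ± 0.042 and 0.154% ± 0.011. The order of the genotypes in S phase depends on the scaling: in TMM CPM the KDM4A means were below the control means in early S (4160 and 4204) and late S (3006 and 3364). The sum was highest in early S in control culture 1 and in both KDM4A cultures, and in late S in control culture 2. The shares are given as values and no test of them was run; an exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 0.333.

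Histone genes differed in their timing. HIST4H4 and HIST2H2BE fell from G1 already in late S, by 1.93 ± 0.33 and 1.85 ± 0.39 in control cells (adjusted p = 0.0128 and 0.0421) and by 2.33 and 1.86 in KDM4A cells. HIST1H2BJ and HIST1H1C also fell by late S in KDM4A cells, by 2.03 and 1.22, whereas HIST1H2BL rose there by 1.30 ± 0.31 (adjusted p = 0.0489). The list's median from G1 to early S was 0.21 in control cells (adjusted p = 0.625) and 0.64 in KDM4A cells (adjusted p = 7.2e-06, and 0.56 with an estimated correlation), but the KDM4A median was 0.309 without KDM4A G1 replicate 2 (adjusted p = 0.229) and 1.07 without replicate 1. None of the 25 tested histone genes passed alone by edgeR in early S; adjusted over the list alone, 3 rose and 1 fell in control cells and 10 rose in KDM4A cells, and with the culture replicate block 6 rose and 4 fell, and 9 rose. In late S the medians were -0.11 in control cells (adjusted p = 0.0352, and 0.727 with an estimated correlation) and -0.02 in KDM4A cells (adjusted p = 0.619). The control median was -0.279 when libraries were scaled by size alone and -0.171 with no filter on low counts, and passed in both. The KDM4A median in late S turned to 0.031 when libraries were scaled by size alone, to 0.104 with a replicate block and to 0.111 with the culture replicate block, and passed in none of these. The control median turned to 0.35 without control culture 1, to 0.09 without control G1 replicate 1 and to 0.02 without control late S replicate 1, and passed in none of these. Without KDM4A G1 replicate 2 the KDM4A median was -0.327 (adjusted p = 0.0198).

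By G2/M, 19 of 25 tested canonical histones had fallen in control and 13 of 25 in KDM4A cells. In control cells the list fell by a median of 1.86, 25 of 25 negative (adjusted p = 1.0e-16, and 0.163 with an estimated correlation; fry 8.3e-04), and 23 genes fell when adjusted over the list alone. In KDM4A cells it fell by a median of 1.34, 23 of 25 negative (adjusted p = 1.1e-09, and 0.266 with an estimated correlation; fry 0.0106), and 17 genes fell when adjusted over the list alone. With HIST1H1A and HIST1H1D, at 0 counts in control G2/M, set to their bounds, the control median was -1.79. HIST2H3D fell by 4.03 ± 0.58 in control and 2.97 ± 0.54 in KDM4A cells (adjusted p = 0.0011 and 0.0052), HIST4H4 by 3.46 and 3.06, and HIST2H2BE by 3.07 and 2.44. HIST1H1C, a linker histone gene, fell by 2.62 and 2.31. The canonical histones with known polyadenylated transcripts fell in G2/M by medians of 2.44 and 1.67 (adjusted p = 1.2e-06 and 2.0e-05, and 0.163 and 0.266 with an estimated correlation), and all 5 fell in each genotype. Without KDM4A G1 replicate 1 the KDM4A medians were -0.891 for the whole list and -1.10 for these 5.

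**Figure D4:**
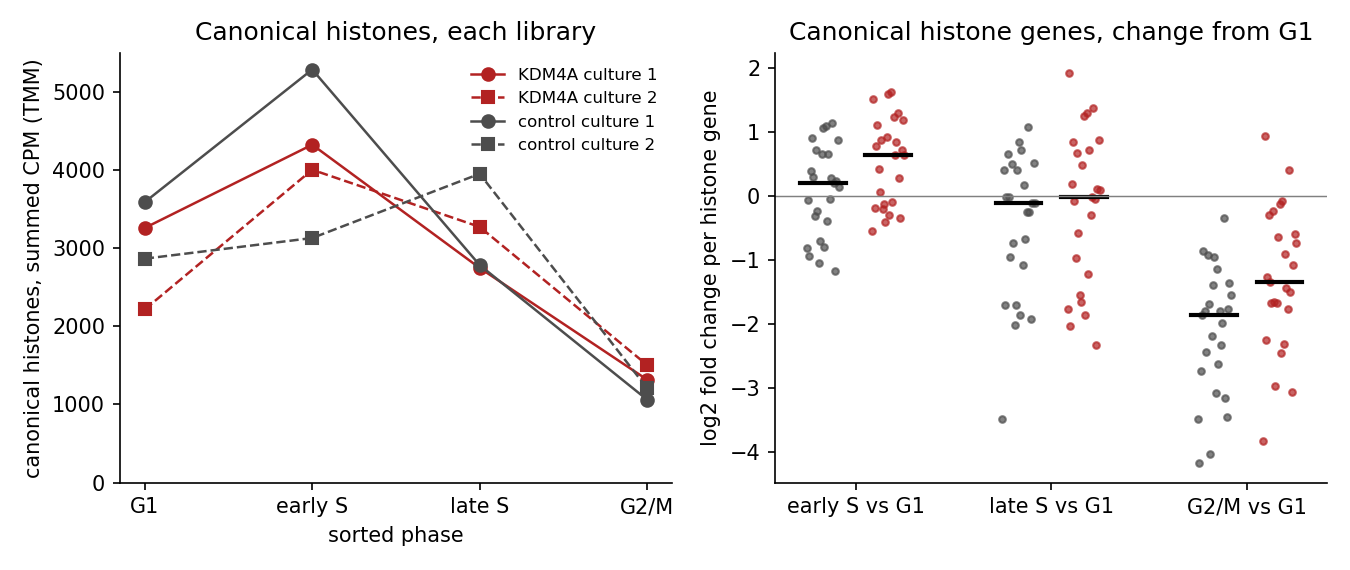
Left, canonical histone genes summed, in TMM CPM, against the sorted phase, 1 point per library and 1 line per culture. Right, log2 fold change from G1 of each of the 25 tested canonical histone genes in control (grey) and KDM4A (red) cells, with the median as a bar; the G2/M medians are -1.86 and -1.34.

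Whether the histone pattern differed between the genotypes was tested within each phase and as a difference of the changes from G1. In G1 the canonical histones were lower in KDM4A cells by a median of -0.32, 21 of 25 negative (adjusted p = 0.0057, and 0.631 with an estimated correlation). In G2/M they were higher by a median of 0.41, 22 of 25 positive (adjusted p = 3.1e-04, and 0.67 with an estimated correlation), also 0.41 with the genes at 0 set to their bounds. With no filter on low counts the G2/M median was 0.371 and did not pass (camera adjusted p = 0.0857). The medians were 0.07 in early S (adjusted p = 0.0992) and -0.12 in late S (adjusted p = 0.566). In late S the mean was 0.12, of the other sign than the median. Scaled by size alone, the median became 0.11 in late S and 0.181 in early S, and neither passed. None of the 25 tested histone genes passed alone in any phase by edgeR. This does not cover the listed histone genes that could not be matched by name. Whether the gene without a name that rose in G1 and early S is one of them could not be told. Over the summed phases the median of 29 tested genes was -0.10 and the mean 0.02 (adjusted p = 0.286), and fry pointed upwards. A fit without control culture 1 leaves 1 control library per phase and takes its spread from the KDM4A groups. Its medians were -0.127 in G1, 0.423 in early S, -0.421 in late S and 0.196 in G2/M. Single libraries moved them too, to -0.581 in G1 without KDM4A G1 replicate 1 and to 0.665 in G2/M without control G2/M replicate 2. The G1 call was lost without control G1 replicate 1 (-0.13, adjusted p = 0.509) and without KDM4A G1 replicate 2 (-0.021, adjusted p = 0.908), and the G2/M call without control G2/M replicate 1 (0.209, adjusted p = 0.394). Early S passed without control early S replicate 1 (0.423, adjusted p = 7.4e-05) and KDM4A early S replicate 2 (0.212, adjusted p = 0.023), and turned to -0.234 without control early S replicate 2 and to -0.096 without KDM4A early S replicate 1. Late S passed without control late S replicate 1 (-0.415, adjusted p = 0.0029) and turned to 0.197 without control late S replicate 2.

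The change of the canonical histones from G1 was more positive in KDM4A cells by a median of 0.39 in early S, 25 of 25 positive, and by 0.70 in G2/M, 24 of 25 positive. The adjusted p were 2.1e-05 and 6.0e-10, and 0.952 and 0.65 with an estimated correlation. The G2/M difference was 0.325 without control culture 1 (adjusted p = 0.0391) and 0.418 without KDM4A G1 replicate 2. In late S the median difference was 0.20 (adjusted p = 0.0788), and it turned to -0.268 without control culture 1 (adjusted p = 0.0489), to -0.081 without KDM4A G1 replicate 2 and to -0.067 without control late S replicate 1. It passed, at 0.545, 0.342 and 0.528, without KDM4A G1 replicate 1, control G1 replicate 2 and control late S replicate 2. Other replication lists went the same way. The S phase genes differed by 0.22, 0.32 and 0.28 in early S, late S and G2/M, and the origin licensing and firing genes by 0.26, 0.29 and 0.32, with adjusted p of 0.0079 or less and from 0.684 to 0.952 with an estimated correlation. Without control G1 replicate 1 none of these 6 passed, at -0.028, 0.089 and -0.014 for the S phase genes and -0.002, 0.016 and 0.056 for origin licensing and firing. In early S neither passed without control early S replicate 2, KDM4A G1 replicate 1 or KDM4A early S replicate 2, at -0.011, 0.15 and 0.159 for the S phase genes and 0.124, 0.255 and 0.225 for origin licensing and firing. In late S origin licensing and firing did not pass without control late S replicate 2 (0.205). In G2/M neither passed without control G2/M replicate 2 (0.191 and 0.113), nor did the S phase genes without KDM4A G1 replicate 1 (0.227), KDM4A G2/M replicate 2 (0.177) or control culture 1 (0.139). The highest values on leaving out 1 library were 0.564 for the S phase genes in late S and 0.559 for origin licensing and firing in early S, both without control G1 replicate 2. Scaled by size alone the late S differences were 0.508 and 0.485. The fits without a library had no culture block, so each brings a difference between cultures into the change. Within cultures, medians of the S phase genes in early S were 0.281 and 0.279 in control and 0.55 and 0.535 in KDM4A. They were 0.032 and 0.411 against 0.527 and 0.555 in late S, and -0.121 and 0.102 against 0.193 and 0.224 in G2/M. Both KDM4A cultures lay above both control cultures each time, from the same G1 libraries, and this was not tested. Gene by gene, edgeR found 0 genes in each single difference and 0 with the 3 differences tested together, with 159, 132, 135 and 56 at an unadjusted p under 0.05. DESeq2 and the culture replicate block also gave 0 for each single difference. The early S difference of the histones no longer passed without control G1 replicate 1 (0.297, adjusted p = 0.0998), control early S replicate 2 (0.243, adjusted p = 0.721) or KDM4A G1 replicate 2 (0.156, adjusted p = 0.473), and was 0.741 and 0.813 without control early S replicate 1 and KDM4A G1 replicate 1.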

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

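The lists, comparisons and alternatives were set before the data were examined; the tests of foreign cells, of sorting, of the G1 fraction and of structural RNA, those with protein-coding genes alone and those without control culture 1 were chosen only after the result was seen. So were 2 readings: taking means in the pairings of cultures, and asking whether single cultures overlap in the test of the G1 fraction. In 14 of 90 list tests the change from G1 differed between KDM4A and control cells with the preset correlation. All 14 are lost with an estimated correlation, where the adjusted p lie between 0.65 and 0.952. That test was taken from the fit without the culture replicate block. It did not call the fall of all canonical histones from G1 to G2/M in either genotype. Losing a call there is therefore no evidence that the genotypes changed alike. In early S the median differences were 0.492 for the canonical H2B genes, 0.387 for all canonical histones, 0.221 for the S phase genes and 0.263 for origin licensing and firing. In late S they were 0.319 for the S phase genes, 0.290 for origin licensing and firing and 0.306 for homologous recombination and fork protection. In G2/M they were 0.756 for the canonical H2A genes, 0.686 for H2B, 0.700 for all canonical histones and 0.628 for those with known polyadenylated transcripts. The G2/M differences were 0.284 for the S phase genes, 0.317 for origin licensing and firing and 0.149 for homologous recombination and fork protection. All 14 are positive, so the change from G1 was more positive in KDM4A cells; this says nothing of the levels, which were lower in G1 for the canonical histones and the S phase genes. On leaving out 1 library at a time, 11 of the 14 lost their call at least once. Kept were homologous recombination and fork protection in late S and, in G2/M, all canonical histones and H2B, of which H2B was lost without control culture 1. The lists share members and every difference starts from the same G1 libraries, so they are not independent. The fits without a library had no culture block, so a culture then lacked its own G1 or later phase. A call lost there can come from a difference between cultures as well as from reliance on that library.

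The pattern in the canonical histones was that they fell less from G1 to G2/M in KDM4A cells as a group. Per culture the medians were -2.05 and -1.50 in control and -1.57 and -0.78 in KDM4A cells, so single cultures overlap. Structural RNA taking up the counts is argued against: it would move all other genes alike, but with libraries scaled by size alone the median over all genes was 0.0618 and that of the histones 0.794. Poorer separation of the G1 and G2/M fractions in the KDM4A cultures stays open: the median rise of the G2/M genes was 1.61 and 1.72 in the KDM4A cultures, and 1.67 and 1.43 in the control cultures, so the ranges overlap. A different G1 fraction, with fewer cells already making histone mRNA, may account for part of it. Measured from the mean of the S phase fractions in place of G1, the difference was 0.349 against 0.711 from G1, just under its midpoint, and both KDM4A cultures (-1.51 and -1.36) lay above both control cultures (-1.92 and -1.70). Reads in no gene also rose more from G1 to G2/M in both control cultures than in both KDM4A cultures. Whether this bears on the histones was not tested. An effect of KDM4A on histone mRNA stays open as well and was not tested apart from these.

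Control culture 1 stood apart from the other 3 cultures. In all 4 phases 49 genes differed at least 4-fold from every other culture, 35 of them lower and 14 higher, against 1 to 7 genes for each of the other cultures. Sequencing depth and structural RNA are argued against: with protein-coding genes alone and every library thinned to 5260007 counts, 33 genes lay at that distance, 32 of them among the 49, against at most 7 in another culture. Foreign cells mixed into control culture 1 are argued against as well, unless they gave 75% or more of its RNA, since a mixture lowers a transcript only by their share. Of the genes of moderate level, 20 were 4-fold or more lower there in all phases and 1 was higher, against 0 lower in each other culture. An earlier bound, 10 such genes 8-fold lower, was not reached at 4 and was replaced after the values were seen. A culture made up mostly of other cells, or a difference between lines or passages, may be the source; these 4 cultures cannot show which, and neither was tested.

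Several genes were near 0 in the control cultures and present in the KDM4A cultures. Divergence between lines whatever the genotype would make other pairings of the 4 cultures give as many genes, and it stays open. Taking the means of the sides, 7 genes were 8-fold or more apart in the same direction in all 4 phases between control and KDM4A, against 4 and 5 in the other pairings. The 7 include KDM4A itself, and 1 of them was lower in KDM4A cells. MMP1 was counted in every pairing, since a single culture can move the mean of its side. These counts therefore do not hold only genes that separate both cultures of a side. Requiring every culture of a side to be 8-fold apart from every culture of the other, there was 1 gene, CHFR, against 0 and 0. At 4-fold, a bound chosen after the result was seen, there were 41 genes by means, against 19 and 20, and 9 by every culture, against 0 and 1. An effect of KDM4A on these genes stays open too.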

How the results depend on the processing

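Protein-coding genes alone, the fits without control culture 1 and the crossed block were chosen only after the result was seen. Calls between KDM4A and control cells depended on the processing most. In G1, early and late S and G2/M the counts, 7, 6, 6 and 4 in the report, were 131, 92, 143 and 171 with no filter on low counts, 20, 14, 14 and 14 with DESeq2, and 22, 10, 15 and 18 with a replicate block. With the crossed replicate block early S gave 8. With the 4 libraries of the phase alone they were 5, 0, 0 and 0, where far fewer degrees of freedom were left. Library size alone gave 10 in late S and 8 in G2/M. Without control culture 1 there were 13 in G1, 4 of them shared, 6 in early S, 6 in late S and 10 in G2/M, 2 shared in each. Leaving out 1 library gave 0 (control G1 replicate 2) to 5 (KDM4A G1 replicate 1) in G1, 0 (control early S replicate 2) to 5 in early S, 0 (either control late S library) to 4 in late S, and 0 (control G2/M replicate 1) to 4 in G2/M. With the phases summed, 1 gene became 11 with library size alone, 251 with no filter, 39 with DESeq2, 132 as the average of the within-phase contrasts and 0 with protein-coding genes alone, while the replicate block kept 1. Without control culture 1 it was 64; leaving out single cultures gave 3 (KDM4A culture 2) to 1341 (control culture 2). Of the genes named by symbol that passed, none changed sign under any alternative that was run for it. The causes of these moves were not tested.

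Phase calls moved in number and in part in their genes. Every call was also made with the culture replicate block, but in control cells without control culture 1 only 35 of 150 in early S, 105 of 145 in late S and 989 of 1857 in G2/M were shared, and with DESeq2 142, 144 and 1770. In KDM4A cells DESeq2 shared 30 of 31, 268 of 277 and 1077 of 1168. The share of early S calls that rose in control cells was 71.3% with the culture replicate block. From G1 to early S in control cells, 150 genes became 67 with library size alone, 360 with no filter, 677 with DESeq2, 433 with a replicate block, 1900 with the culture replicate block and 82 without control culture 1, and leaving out 1 library gave 0 to 392. To late S, 145 became 234 with no filter, 306 with DESeq2 and 894 with the culture replicate block, with 31 to 118 on leaving out a library. To G2/M, 1857 became 5154 with the culture replicate block, and 347 (control G1 replicate 1) to 1055 on leaving out a library. In KDM4A cells, 31 in early S became 156 with no filter, 176 with DESeq2, 74 with a replicate block, 703 with the culture replicate block and 423 without control culture 1, and 0 or 1 on leaving out a library. In late S, 277 became 463, 499 and 1577 with no filter, DESeq2 and the culture replicate block, 1006 without control culture 1, and 84 (KDM4A G1 replicate 1) to 124 on leaving out a library. In G2/M, 1168 became 1758 with a replicate block, 4369 with the culture replicate block and 3573 without control culture 1, and 228 (KDM4A G1 replicate 1) to 758 on leaving out a library. Differences between genotypes stayed at 0 genes except with no filter, where they were 1, 3 and 1 in early S, late S and G2/M and 3 together. Library size alone moved the median of all genes by 0.12 in early S, 0.21 in late S and 0.11 with phases summed between genotypes, by -0.14 from G1 to late S in control cells and by 0.12 from G1 to G2/M in KDM4A cells, and by 0.10 and 0.19 in the early S and late S differences. The share of calls that rose then went from 89.0% to 76.3% in late S and from 63.9% to 74.7% in G2/M in control cells, and from 70.5% to 89.4% in G2/M in KDM4A cells.

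The canonical histone medians between genotypes rested on control culture 1 and on single libraries. Without control culture 1 the medians were -0.127 in G1, 0.423 in early S, -0.421 in late S and 0.196 in G2/M. That fit leaves 1 control library per phase and takes its spread from the KDM4A groups. With no filter on low counts the G2/M median was 0.371 (camera adjusted p = 0.0857). Leaving out 1 library gave -0.581 to -0.021 in G1 (without KDM4A G1 replicates 1 and 2), -0.234 to 0.423 in early S (control early S replicates 2 and 1), -0.415 to 0.197 in late S (control late S replicates 1 and 2) and 0.209 to 0.665 in G2/M (control G2/M replicates 1 and 2). From G1 to late S in control cells the median, -0.11, reversed to 0.347 without control culture 1, 0.087 without control G1 replicate 1 and 0.021 without control late S replicate 1, with -0.390 as the lowest, without control late S replicate 2. In KDM4A cells leaving out G1 replicates 2 and 1 gave 0.309 and 1.07 in early S and -0.327 and 0.439 in late S. The difference between genotypes was 0.156 to 0.813 in early S and -0.081 to 0.545 in late S on leaving out the same libraries; in late S it reversed to -0.268 without control culture 1 (adjusted p = 0.0489) and was 0.222 with protein-coding genes alone (adjusted p = 0.0315). The falls in G2/M in each genotype and their difference (0.325 without control culture 1, to 0.989 without control G2/M replicate 2) kept their sign under every alternative that was run, and their call with the preset correlation. Of 421 list tests 112 were called with the preset correlation, 9 with an estimated one and 37 with fry. With the 10 most counted genes out of the total, the histone shares in G1, early and late S and G2/M were 0.3975%, 0.5397%, 0.4218% and 0.1449% in control cells, and 0.3388%, 0.5432%, 0.3847% and 0.1834% in KDM4A cells. A smaller total raises every share by construction, but 2 orders also turned: control late S came to lie above control G1, and above KDM4A late S. The cause was not tested. Depth limits genes such as CHFR and MSRB1, whose control counts of 0 to 4 per library set no exact fold change.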

Other observations

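The genes of control culture 1, the pairing of cultures and the lists below were looked at only after the result was seen. Control culture 1 held far less of several transcripts than the other 3 cultures. DNAJC15, a mitochondrial co-chaperone gene, stood at a mean of 0.206 CPM over its 4 phases, against 25.7 in control culture 2 and 26.2 and 28.4 in the KDM4A cultures. FRAS1, a basement membrane gene, stood at 0.360 against 27.5, 11.6 and 22.7, and the desmosomal gene DSP at 3.59 against 68.8, 64.8 and 57.3. The small heat shock gene HSPB8 and the protocadherin gene PCDHGA11 were also lower there, at 0.623 against 8.39 to 11.8 and at 0.987 against 9.10 to 18.3. The sialyltransferase gene ST6GAL2 went the other way, at 98.0 in control culture 1 against 10.2 to 12.2.

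Genes outside the named lists of the report also followed the phase. POU2F1, a transcription factor gene of histone promoters, rose from G1 to G2/M by 1.85 ± 0.19 in control and 1.69 ± 0.20 in KDM4A cells (adjusted p = 1.6e-04 and 2.1e-04). KLF6, an immediate early gene, rose by 1.26 and 1.78, and the translesion polymerase gene POLH by 1.26 and 1.59. EHMT2, which encodes a methyltransferase of histone lysines, fell by 0.80 and 0.60, and CBX5, which encodes a heterochromatin protein, rose by 1.16 and 0.88. In late S the histone chaperone and chromatin assembly genes had a median of 0.19 in KDM4A cells over 20 genes (adjusted p = 0.0035, and 0.329 with an estimated correlation). The glycolysis and hypoxia response genes were lower in G2/M by medians of -0.28 in each genotype (adjusted p = 0.0304 and 0.005, and 0.218 and 0.235 with an estimated correlation). In control cells this list did not pass without control G2/M replicate 1 (-0.231), control G1 replicate 2 (-0.168) or control culture 1 (-0.327), nor with the culture replicate block (adjusted p = 0.0505), and the KDM4A median was -0.158 when scaled by size alone. The median of the chaperone list was 0.305 without KDM4A late S replicate 1.

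Per culture, the canonical histones changed from G1 to early S by medians of 0.24 and 0.08 in control cultures 1 and 2, and by 0.53 and 0.90 in KDM4A cultures 1 and 2. These ranges did not overlap. Those for late S did, at -0.587 and 0.329 in the control and -0.201 and 0.354 in the KDM4A cultures. From G1 to G2/M the medians were -2.05 and -1.50 in the control cultures and -1.57 and -0.78 in the KDM4A cultures, so the ranges of the genotypes overlap. These are values of single cultures and were not tested.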
